A study of Mus musculus with 6 samples.

How the data were processed

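Poly(A) RNA from whole pancreatic islets of 6 mice aged 5 weeks was sequenced, 1 library per animal code. The mice were 3 animals whose floxed Abca12 allele had been deleted by Rip1-Cre, a recombinase driven by the rat insulin promoter (KO), and 3 Cre-carrying controls heterozygous for the floxed allele (HET). Groups were taken from the genotype labels. Replicates were numbered within each group in the order of the records, so the numbers pair no libraries.

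Per the submitters' processing notes, HISAT2, DESeq2 and the GRCm38 mouse genome were used, with versions and roles not given. The counting program, the annotation and the strandedness are not given in the sources used here. The deposited expression values are on a log2 scale, 1 per gene and library, for 34245 genes. In each library the lowest log2 value was shared by all genes without reads, and the remaining deposited values lay at whole multiples of 1 read. Genes without reads had been written as 0.9 read by the authors. Of 93649 values under 1000 reads, 100% lay within 0.01 read of a whole number, so the deposited log2 values were read as log2 RPM, reads relative to the total of the library. The authors' deposited table also gives a difference on the log2 scale and a fold change, a ratio of HET over KO, which is the opposite direction to the KO minus HET differences used here. A deposited sheet of 3 genes gives the authors' corrected p-value, whose test and correction are not stated per the file headers.

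The RPM denominator of each library, recovered from these steps, was 27447026 to 35511008 reads, and the listed genes held 18885055 to 23504922 of them. A value of 3 reads corresponded to 0.0845 to 0.109 RPM. Limits of this kind cover counting error only. The positions of 29429 genes (85.9%) were identical to those of GENCODE M21, from which gene identifiers were taken.

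The design fixed before the data were examined assumed a count test if counts were deposited and limma otherwise. As the values are on a log2 scale, the main test was limma's moderated test with a mean-variance trend and robust moderation (limma 3.58.1, R 4.3.3) on log2(RPM + 1). Genes with a mean of at least 1 RPM entered it, which left 14238. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are on the log2(RPM + 1) scale, which understates changes of genes with few reads. Each library has its own animal code in the labels; KO 2 held both Xist and Y-linked RNA, so that library is not shown to come from a single animal.

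A total of 38 gene lists covering islet and other cell types, lipid pathways, secretion, stress and strain background were written before the data were examined. Lists with at least 5 genes tested were compared with all other genes by camera with a preset correlation of 0.01. Camera with an estimated correlation and fry were fixed as the other tests. Camera's preset value is far below the correlation within some lists, which makes its p-values too small there. The acinar share was compared by an exact two-sided permutation test, for which 3 against 3 libraries allow no p below 0.1.

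Named genes followed a rule fixed before the data were examined. It took Abca12, up to 12 genes per direction past the threshold or, failing that, the 8 with the lowest p per direction, and the 2 members of each list with the lowest p where none passed. It added 15 islet and lipid genes and the genes of the deposited sheet. The text gives values for part of these genes, picked after they were seen. Results for 4 others under this rule, including those under alternatives, and for 1 gene list are not reported here. Genes from outside the rule are identified as such where they appear.

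On simulated data with the spread of these libraries (14191 genes, 50 changed genes per fold size), limma called 26% of genes changed 2-fold, 70% of those changed 4-fold and 90% of those changed 8-fold. Of all its calls there, 6.58% were unchanged genes. Simulated genes were drawn independently, without the axis shared across genes in the real libraries, and changes of all sizes were present together. These rates may therefore overstate the power of the real comparison. No 2 libraries of a group held the same counts: chi-square per degree of freedom ran from 17.8 to 227.5.

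Alternatives covered other scaling factors, filters, pseudocounts, thresholds, covariates, limma-voom on the recovered reads and leaving out each library. A DESeq2 Wald test was not used. Figures were drawn with matplotlib 3.10.9.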

Results

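Islet RNA was compared between 3 mice lacking Abca12 in Cre-expressing beta cells (KO) and 3 heterozygous controls (HET), all aged 5 weeks. Abca12 belongs to the ABCA family of lipid transporters. The comparison asks which islet transcripts depend on the gene. Library totals were 29186296, 29739290 and 27447026 reads in KO 1 to 3, and 30934062, 35511008 and 33158348 reads in HET 1 to 3. Every KO library was thus shallower than every HET library.

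Abca12 (ENSMUSG00000050296.14, chromosome 1, 71242276 to 71414910, GRCm38) was at the limit of detection in whole islets. KO 1 held 2 reads and the other 5 libraries held 0. The means were 0.0228 ± 0.0396 RPM (SD, n = 3) in KO and 0 in HET, where 3 reads over the group correspond to 0.0301 RPM. Loss of the transcript was therefore not detectable at this depth, and the genotype labels could not be checked from it.

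No gene passed the threshold between KO and HET islets in limma, and the lowest adjusted p was 0.9998. Of 14238 genes, 250 had an unadjusted p under 0.05, 183 of them higher and 67 lower in KO, where chance alone would give 712. The share of such genes that were higher, 73.2%, was 49.6% with median-of-ratios scaling, 63.3% with upper quartile scaling, 49.1% without KO 2 and 40% without HET 1. The libraries also split along an axis described below. Under a block for that split, chosen after seeing the data, 767 genes had an unadjusted limma p under 0.05 (lowest adjusted p 0.0965). Adding the acinar share as a covariate instead gave 991 (lowest adjusted p 0.199). No gene passed in either fit. The groups did not overlap for 817 genes (5.74%), against 10% by chance. A limma-voom fit with sample quality weights was planned without a set library size or moderation. Of its 6 versions, 5 called 0 genes, the version run first among them; the version then adopted, with the RPM denominators, called 407 genes, 214 of them higher in KO (lowest adjusted p 0.0497). The 6 versions without the weights called 0.

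The genes with the lowest p toward higher RNA in KO were led by Fbxw15, an F-box protein gene. Fbxw15 (ENSMUSG00000074060.10, chromosome 9, 109552602 to 109568262) had 6.28 ± 0.798 RPM in KO and 2.05 ± 0.202 RPM in HET (SD, n = 3 each), a log2 difference of 1.25 (95% interval 0.82 to 1.68). Its neighbour Gm42755 differed by 1.21 (0.54 to 1.87). Fmo1, a flavin-containing monooxygenase gene, ranged from 198.0 to 264.1 RPM in KO and 102.8 to 121.4 RPM in HET, a log2 difference of 1.00 (0.58 to 1.43). Gipr, the receptor for the incretin GIP, had 102.9 ± 27.2 and 49.6 ± 1.34 RPM, a difference of 1.00 (0.51 to 1.50). Exo5, a DNA exonuclease gene, differed by 0.81 (0.40 to 1.21). The unnamed transcripts 6720427I07Rik, Gm10637 and Gm37583 differed by 0.88, 0.91 and 1.74. The 3 KO libraries lay above the 3 HET libraries for all 8 genes, which picking the lowest p in these libraries largely brings about. None of the 8 passed the adjusted threshold.

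The genes with the lowest p toward lower RNA in KO were led by Nupr1, a stress-induced chromatin protein gene. Nupr1 (ENSMUSG00000030717.9, chromosome 7, 126623249 to 126630861) had 43.9 ± 15.2 RPM in KO and 110.4 ± 11.4 RPM in HET (SD, n = 3 each), a log2 difference of -1.36 (95% interval -1.95 to -0.77). Phgdh, the first enzyme of serine synthesis, had 19.1 ± 1.15 and 32.9 ± 1.47 RPM, a difference of -0.76 (-1.10 to -0.42). Cebpb, a stress-responsive transcription factor gene, differed by -0.91 (-1.50 to -0.32). Gpr135, Scarf2 and Rasgef1b differed by -1.11, -0.84 and -0.57. AC154747.3 and Gm15063 differed by -0.70 and -0.56. These 2 transcripts lie over Txndc5 and Rab39b, and Cebpb over Tmem189, on the opposite strand, so reads cannot be assigned without strand information. None of the 8 genes passed the adjusted threshold.

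**Figure D1:**
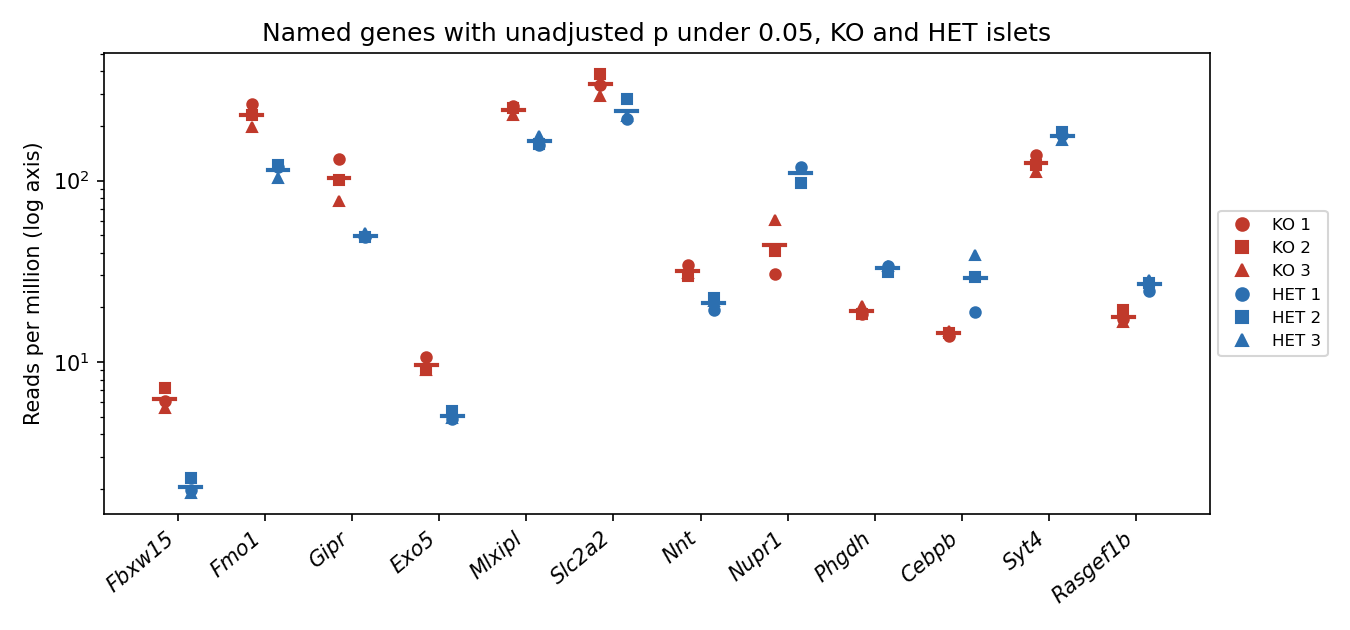
Read abundance in RPM (log axis) of 12 named genes with unadjusted p under 0.05, chosen for display after their values were seen; symbols are libraries, bars are group means. Fbxw15 lies at 5.61 to 7.16 RPM in KO and 1.90 to 2.28 RPM in HET, and no plotted gene passed the adjusted threshold.

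The authors' deposited table lists 3 genes with corrected p-values. In the authors' deposited table, Nupr1 had a HET over KO fold change of 2.61 (corrected p = 0.009) and Fbxw15 one of 0.327 (corrected p = 0.001). The third, the histone gene Hist1h2bn, had a fold change of 0.0482 (corrected p = 0.007) in the authors' deposited table. Hist1h2bn (chromosome 13, 21754123 to 21754503) had 63, 39 and 32 reads in KO 1 to 3 and 5, 0 and 3 reads in HET 1 to 3. Its means were 1.55 ± 0.536 and 0.084 ± 0.081 RPM (SD, n = 3 each), below the filter over all libraries. With no filter limma gave it a log2 difference of 1.21 (0.78 to 1.65) and an adjusted p of 0.98. This value is on log2(RPM + 1), which shrinks differences at such low levels, so it cannot be set against the authors' fold change. No count test was run on the recovered reads of this gene.

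Genes of beta cell identity were higher in KO than other genes as a group, by a small amount. Of 27 members, 22 were higher and 5 lower, with a median log2 difference of 0.20 (camera adjusted p = 0.0236 with the preset correlation). With an estimated correlation, 0.00798 for this list, the camera p was 0.0398 unadjusted and 0.936 adjusted over the lists. Fry gave 0.041 unadjusted and 0.991 adjusted. Slc2a2, the glucose transporter of beta cells, had 338.4 ± 47.8 RPM in KO and 242.4 ± 33.8 RPM in HET (SD, n = 3 each), a difference of 0.48 (0.02 to 0.94). The insulin genes Ins1 and Ins2 differed by 0.23 (-0.32 to 0.78) and 0.18 (-0.41 to 0.76). Mafa and Pdx1, transcription factors of mature beta cells, differed by -0.57 (-1.70 to 0.56) and 0.14 (-0.34 to 0.63). Iapp, the amyloid peptide gene, differed by -0.07 (-0.84 to 0.70). No member passed over all genes or adjusted over the list alone, and the list's call was lost without KO 1, KO 3, HET 1 or HET 3 (adjusted p up to 0.189), with no filter on low values (0.125) and by limma-voom (0.0605).

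Markers of the other endocrine cells did not pass in the main test. Alpha cell markers had 6 of 12 members higher in KO (camera adjusted p = 0.480). Gcg, the glucagon gene, differed by 0.29 (-0.62 to 1.21) and Ttr by 0.57 (-0.01 to 1.15). Delta and PP cell markers had 6 of 9 members higher (camera adjusted p = 0.480). Sst and Ppy, their hormone genes, differed by 0.27 (-0.33 to 0.88) and 0.20 (-0.66 to 1.07). With a block for the split of the libraries described below, chosen after seeing the data, both lists passed toward higher RNA in KO with the preset correlation (adjusted p = 0.0059 and 0.0162) and neither with an estimated correlation (0.758 for both). By fry with the block, delta and PP cell markers passed (0.0428) and alpha cell markers did not (0.639). Alpha cell markers also passed camera without HET 2 (0.0446).

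**Figure D2:**
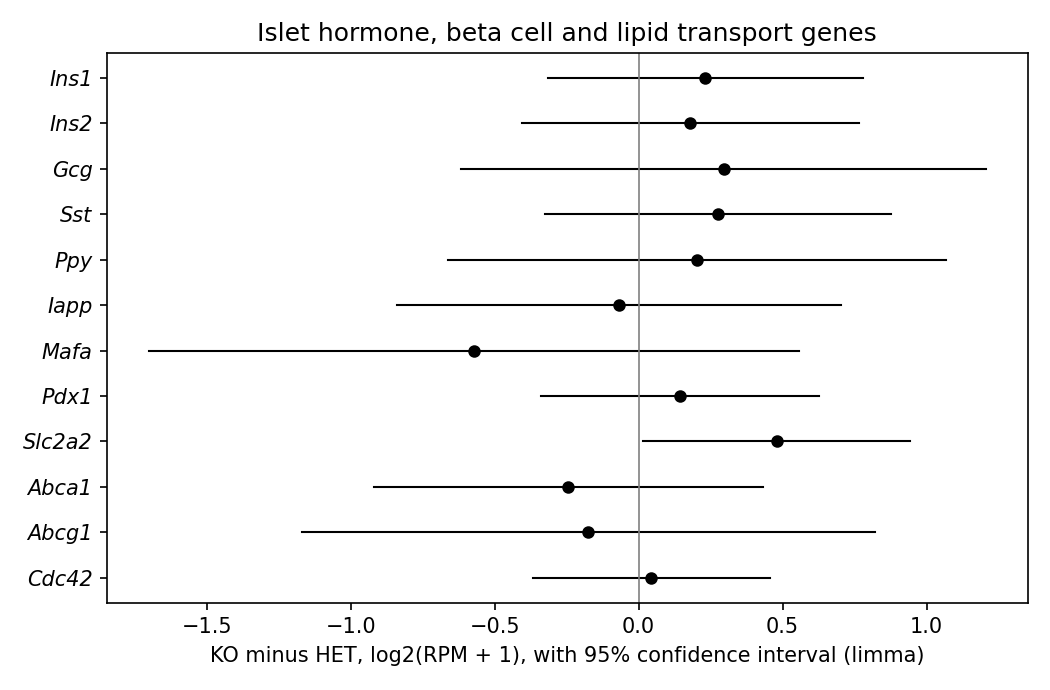
Difference between KO and HET islets in log2(RPM + 1) for 12 of the 15 islet and lipid genes fixed before the data were examined; points are limma estimates over 3 KO and 3 HET libraries and lines are 95% intervals. The interval excludes 0 for Slc2a2 (0.02 to 0.94), which did not pass the adjusted threshold.

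Lipid genes were the groups closest to the function of an ABCA transporter, and none of their lists passed in the main test. Cholesterol biosynthesis had 19 of 25 members higher in KO, with a median of 0.12 (camera adjusted p = 0.0968). Cyp51 and Dhcr7, enzymes of that pathway, differed by 0.36 and 0.26. Cyp51 lies over Akap9 (61.8 RPM) on the opposite strand, so reads in the overlap cannot be assigned without strand information. Targets of the sterol receptor LXR had 9 of 15 members higher (camera adjusted p = 0.837). The cholesterol exporters Abca1 and Abcg1 differed by -0.24 (-0.92 to 0.43) and -0.18 (-1.17 to 0.82). Fatty acid oxidation and PPAR targets had 14 of 18 members higher (camera adjusted p = 0.0812), with Ehhadh, a peroxisomal oxidation enzyme, at 0.64 (0.11 to 1.18). Fatty acid synthesis had 7 of 19 members higher (camera adjusted p = 0.706). Mlxipl, which encodes the glucose-responsive factor ChREBP, differed by 0.57 (0.19 to 0.96). Sphingolipid genes and the ABCA family had 15 of 32 and 4 of 7 members higher (camera adjusted p = 0.837 for both). With the block, cholesterol biosynthesis and fatty acid oxidation passed toward higher RNA in KO with the preset correlation (adjusted p = 0.0169 and 0.0120). Neither passed with the block and an estimated correlation (0.991 and 0.906). Both also passed with the preset correlation and the acinar share as a covariate (0.0167 and 0.0366), cholesterol biosynthesis without HET 2 (0.00729), and fatty acid oxidation without KO 2 (0.0466) or HET 3 (0.0421).

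Of 36 lists tested, 4 besides beta cell identity passed camera with the preset correlation, and none passed with an estimated correlation or by fry (adjusted p = 0.936 and 0.991 for each of the 4). Of 21 antioxidant response genes, 21 had lower means in KO, with a median of -0.31 (preset adjusted p = 0.00687, estimated 0.936). Of 12 heat shock proteins, 12 had higher means, with a median of 0.79 (preset 0.00698, estimated 0.936). Of 13 genes of the lactogen response of islets, 11 had higher means, with a median of 0.47 (preset 0.00698, estimated 0.936). Of 6 Schwann cell and neuron markers, 6 had higher means, with a median of 0.50 (preset 0.0102, estimated 0.936). No member of these lists passed over all genes, and 1, Ehhadh in the lactogen list, had an unadjusted p under 0.05. The estimated correlations between members were 0.782, 0.970, 0.726 and 0.454 in the same order. The antioxidant call was lost without KO 2 or HET 3 (adjusted p up to 0.237) and the Schwann cell call without KO 2 (0.221). The heat shock and lactogen calls were lost without KO 1, KO 2, HET 2 or HET 3 (up to 0.32 and 0.215).

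The 6 libraries differed from one another along an axis that held both genotypes on each side. The first principal component held 70.5% of the variance and put KO 1, KO 2 and HET 1 on one side and KO 3, HET 2 and HET 3 on the other. Heat shock protein levels, centred on the mean of all libraries, were 0.98, 1.05 and 1.13 on the first side and -0.77, -1.23 and -1.17 on the second. Antioxidant levels were -0.46, -0.61 and -0.69 on the first side, and 0.47, 0.54 and 0.75 on the second. With this split as a block, chosen after seeing the data, the camera adjusted p was 0.977 for both lists and 0.889 for the lactogen response. It was 0.0925 for Schwann cell markers and 0.0162 for beta cell identity. With the block and an estimated correlation no list passed (0.758 for beta cell identity).

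**Figure D3:**
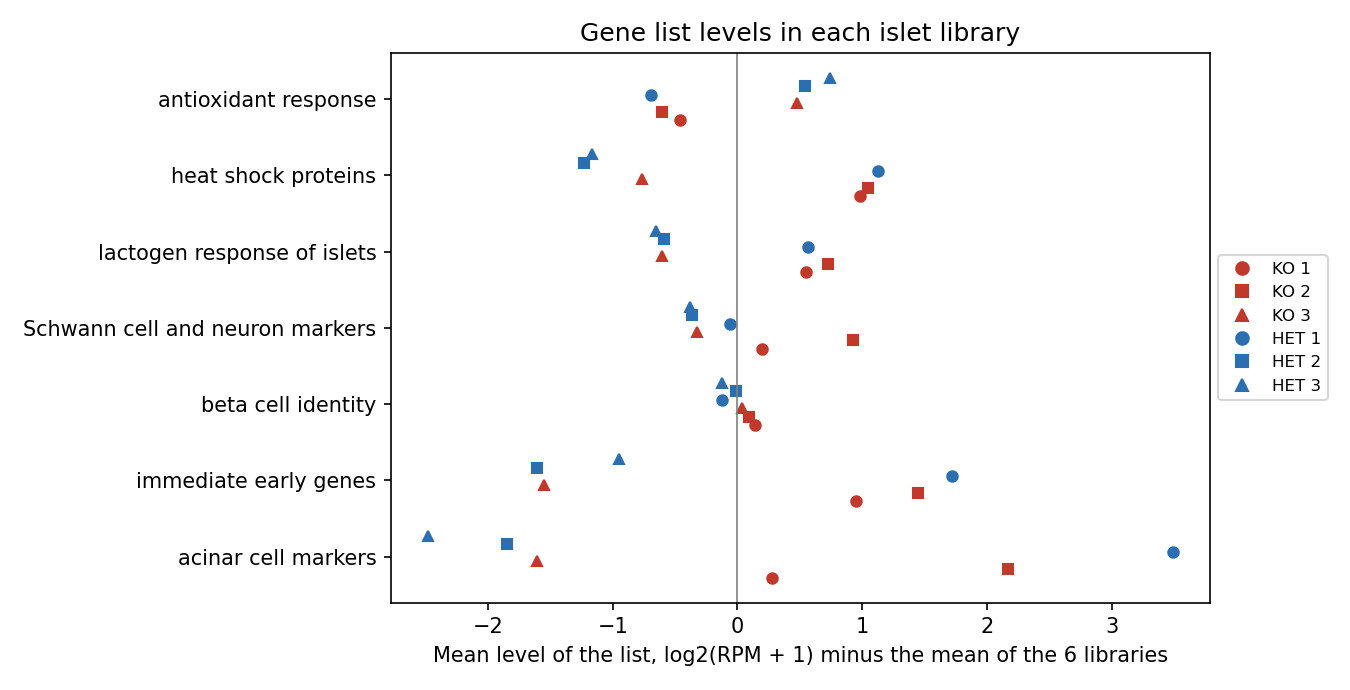
Mean level of 7 gene lists in each library, as log2(RPM + 1) minus the mean of the 6 libraries; colours are genotypes and symbols are replicates. Immediate early genes lie at 0.95 to 1.72 in KO 1, KO 2 and HET 1 and at -1.61 to -0.95 in KO 3, HET 2 and HET 3.

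Acinar RNA carried in the preparations varied more between animals than between the group means. Acinar transcripts made up 0.713%, 2.69% and 0.172% of listed reads in KO 1 to 3 and 6.52%, 0.153% and 0.0890% in HET 1 to 3. The means were 1.19% ± 1.33 and 2.25% ± 3.69 (SD, n = 3 each; exact two-sided permutation test, p = 1, smallest possible 0.1). The difference of -1.06 percentage points turned to 1.07 without HET 1. Of 27 acinar markers, 24 had higher log-scale means in KO, with a median of 0.60 (camera adjusted p = 0.388). With the block the median was -0.88 (preset adjusted p = 1.83e-10, estimated correlation 0.991). The markers passed as higher in KO by limma-voom (2.57e-10) and without KO 3 (0.00767) or HET 1 (9.42e-14), and as lower without HET 3 (0.016). Clps, encoding pancreatic colipase, ranged from 4.04 RPM in HET 3 to 870.5 RPM in HET 1. Duct, endothelial, and stellate and fibroblast markers had 13 of 17, 9 of 16 and 9 of 17 members higher in KO (camera adjusted p = 0.480 for duct markers and 0.837 for the others). Macrophage markers had 14 of 20 higher (camera adjusted p = 0.573) and passed by limma-voom (0.00449) and without KO 3 (0.0472) or HET 1 (0.0483).

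Stress, secretion and growth lists did not pass in the main test, but some did under alternatives with the preset correlation. ER stress genes had 16 of 27 members lower in KO (camera adjusted p = 0.0593). Trib3, a stress-induced pseudokinase gene, differed by -1.16 (-2.63 to 0.30) and Edem1, which acts in ER protein degradation, by -0.30 (-0.70 to 0.09). Insulin granule exocytosis genes had 17 of 37 higher (camera adjusted p = 0.837), with Syt4, a synaptotagmin gene, at -0.51 (-0.90 to -0.12). Cdc42 differed by 0.04 (-0.37 to 0.46). Apoptosis and p53 genes had 12 of 23 higher (camera adjusted p = 0.837). Cell cycle genes had 14 of 28 higher (camera adjusted p = 0.899). Immediate early genes had 25 of 29 loci higher (camera adjusted p = 0.114), with 2 loci for Junb; with 1 locus per symbol, chosen after seeing the data, 24 of 28 were higher (0.136). With the block, immediate early genes turned to lower RNA in KO (median -0.51, preset adjusted p = 1.83e-10) and ER stress genes had a median of -0.23 (9.58e-10). Neither passed with the block and an estimated correlation (0.758 for both). ER stress genes also passed, as lower in KO, with no filter (0.0436), with the acinar covariate (0.000214) and without KO 1, KO 2, HET 2 or HET 3 (0.0367, 0.0227, 5.65e-07 and 0.000954). They did not pass without KO 3 or HET 1. Their centred levels were -0.03, 0.12 and -0.25 in KO 1 to 3, and 0.53, -0.30 and -0.07 in HET 1 to 3. HET 1 thus stood above the rest, and HET 2 was the lowest library. Immediate early genes passed as higher by limma-voom (6.43e-10) and without KO 3 or HET 1 (9.36e-06 and 2.41e-07). Cell cycle genes passed as higher without KO 1 (7.98e-05). Lysosome and oxidative phosphorylation genes had 19 of 24 and 22 of 29 lower (camera adjusted p = 0.0593 and 0.0595). Lysosome genes passed with upper quartile scaling (0.0453), no filter (0.0436), the acinar covariate (0.0171), limma-voom (0.00492) and the Y-linked covariate (0.0455, chosen after seeing the data), and without KO 1, KO 3 or HET 1 (0.0180, 0.0191 and 0.00248). Oxidative phosphorylation genes passed with no filter (0.0436), limma-voom (0.00311) and without KO 3, HET 1 or HET 2 (3.44e-05, 0.0392 and 0.0435).

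The remaining lists did not pass in the main test either. Genes normally silenced in beta cells had 13 of 17 members higher in KO (camera adjusted p = 0.0593), with the lactate dehydrogenase gene Ldha at 0.35 (-0.15 to 0.84). NF-kB and cytokine response genes had 17 of 22 higher (0.0986), and interferon response genes 18 of 26 lower (0.114), although the interferon genes Irf9 and Stat2 differed by 0.25 and 0.24. Irf9 lies over Rnf31 (27.4 RPM) on the same strand, so reads in the overlap cannot be told apart. With the block the interferon list passed toward lower RNA in KO with the preset correlation (0.00933) but not with an estimated correlation (0.758). It also passed without KO 1 (0.0155) or HET 2 (0.0385). Genes normally silenced in beta cells and NF-kB genes passed by limma-voom (0.00796 and 7.82e-06), without KO 3 (0.00287 and 0.000162) and without HET 1 (0.0307 and 0.000526). Mitochondrially encoded genes passed without HET 1 (0.00906). Dedifferentiation genes had 6 of 11 higher (0.837), with Serpina7 at -0.65 (-1.32 to 0.03). Hypoxia, extracellular matrix and mitochondrially encoded genes had 11 of 19, 13 of 22 and 6 of 10 higher (0.837, 0.837 and 0.727). Genes near Abca12 on chromosome 1 had 10 of 15 lower (0.480). Sex-linked genes had 4 of 6 lower with a median of -0.12, while their mean was 0.62 (0.837). Lymphocyte and adipocyte markers had too few tested members, 2 and 1, for a list test.

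Fits on one side of the split, chosen after seeing the data, also called lists with the preset correlation, each against a lone library. In KO 1, KO 2 and HET 1, these were higher in KO for LXR targets (adjusted p = 0.0287), fatty acid oxidation (0.0284) and extracellular matrix (0.0392). They were lower there for acinar markers (1.46e-47), immediate early (1.64e-13), ER stress (4.51e-13), cell cycle (6.23e-05), mitochondrially encoded (6.23e-05), apoptosis (0.00557), interferon (0.0184) and dedifferentiation genes (0.0284). In KO 3, HET 2 and HET 3, they were higher for acinar (4.37e-12), alpha (0.000725) and delta and PP cell markers (0.00928), mitochondrially encoded (3.25e-07) and cell cycle genes (3.64e-06). They were lower there for the ABCA family (0.0134) and immediate early genes (0.019). Acinar, cell cycle and mitochondrially encoded genes thus passed in opposite directions on the sides. As each side holds a lone library of 1 genotype, HET 1 or KO 3, such calls cannot separate genotype from the level of that library.

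Among 5 tested genes that differ between the C57BL/6J and C57BL/6N mouse substrains, 3 were higher and 2 lower in KO. With the block, 2 were higher and 3 lower. Of the 5, 1 passed adjusted over the list alone and 0 passed over all genes (camera adjusted p = 0.604 for the list). Nnt, a mitochondrial transhydrogenase gene, had 31.7 ± 2.16 RPM in KO and 21.2 ± 1.68 RPM in HET (SD, n = 3 each), a difference of 0.56 (0.20 to 0.92). Wdfy1, on chromosome 1 as Abca12 is, differed by 0.47 (0.04 to 0.90). AC154550.1 lies over Nnt on the same strand, so their reads cannot be told apart. Mrpl44 (14.6 RPM) lies over Wdfy1 on the opposite strand, so reads in that overlap cannot be assigned without strand information.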

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

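The split as a block, the Y-linked covariate, the fits on 3 libraries and the version of limma-voom were chosen after seeing the data, and the other settings before. No gene was called under other scaling factors, filters, pseudocounts, thresholds, covariates or without any 1 library, a range of 0 to 0. Genes were called only by 1 version of limma-voom with quality weights (407) and in fits on one side of the split. Those fits called 53 genes in KO 1, KO 2 and HET 1, and 329 in KO 3, HET 2 and HET 3, each with a lone library in 1 group whose spread is assumed from the other. The limma-voom fit gave weights of 0.368 to KO 3 and 0.231 to HET 1 against 1.2 to 2.36 for the others. The plan fixed neither the library size nor the moderation of that fit; the version run first, with library sizes from tested genes, called 0 genes, and the RPM denominators were then used to match the main test. With library sizes from listed or tested genes, or with plain moderation, the weighted fit called 0 genes (lowest adjusted p 0.0527 to 0.0555). The same weighted fit called 5989 genes for the split along the first component, 2207 for KO 1, HET 2 and HET 3 against the rest, and 0 to 3 for the other 7 splits.

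The 5 lists called by camera became 0 with an estimated correlation, 0 by fry, 9 with the acinar share as a covariate, 11 by limma-voom and 9 with the split as a block (0 with the block and an estimated correlation, 1 by fry with the block). Beta cell identity was lost by limma-voom (0.0605) and with no filter (0.125). They became 12 in KO 1, KO 2 and HET 1 and 8 in KO 3, HET 2 and HET 3. Without 1 library the count ran from 3 to 12. In KO 1, KO 2 and HET 1, heat shock (adjusted p = 0.0867) and antioxidant genes (0.454) turned direction, while in KO 3, HET 2 and HET 3 heat shock genes passed as higher in KO (0.000191). The acinar difference ran from -2.14 to 1.07 percentage points without 1 library. The Abca12 difference ran from 0 to 0.0343 RPM; settings of the gene fit do not enter it.

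Of 1635 values of 97 genes of the naming rule under alternatives, 45 turned direction, 52 passed only in the weighted limma-voom fit or on one side of the split, and 1538 kept both; the cause was not tested. None of these genes had passed in the main test. The log2 difference turned with the acinar covariate for Iapp (0.0223), and by limma-voom for Gcg (-0.15), Ppy (-0.22) and Cdc42 (-0.0931). With the block it turned for Clps (-0.69), Iapp (0.16) and Abcg1 (0.19). In KO 1, KO 2 and HET 1 it turned for Prss3 (-1.03), Clps (-2.13), Cldn3 (0.26), Fabp4 (0.28), Abca1 (0.44), Abca3 (0.19), Pcna (-0.0060), Ccne2 (-0.34), mt-Co1 (-0.0714), mt-Cytb (-0.44), Iapp (0.0813), Mafa (0.36) and Abcg1 (0.36). In KO 3, HET 2 and HET 3 it turned for Cldn4 (-0.30), Kdr (0.0017), Cdh5 (-0.0321), Lyz2 (0.0135), Cd79a (-0.16), Acot7 (-0.11), Slc5a10 (0.0798), Fosl1 (-0.0461), Xist (-4.08), Tsix (-2.27), Iapp (0.24) and Abcg1 (0.0241). Without 1 library the ranges crossed 0 for Gcg (-0.0614 to 0.54), Ppy (-0.0795 to 0.53), Cdc42 (-0.0444 to 0.105), Iapp (-0.32 to 0.16), Abcg1 (-0.60 to 0.0925), Abca1 (-0.58 to 0.0116), Clps (-0.15 to 3.57), Fabp4 (-0.49 to 0.15) and Pdx1 (-0.0286 to 0.30). TMM scaling and a DESeq2 Wald test were not run.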

Other observations

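The tests of the split and of the lists against it, and the ATF4 list itself, were chosen after the first results were seen. Of 35 tested genes induced by ATF4, the transcription factor of the amino acid and integrated stress responses, 32 had lower and 3 higher means in KO, with a median log2 difference of -0.38 (camera p = 0.0663 with an estimated correlation). Slc6a9, a glycine transporter gene, differed by -0.81 (95% interval -1.39 to -0.23) and the aminoacyl-tRNA synthetase gene Eprs by -0.46 (-0.91 to -0.02). Psat1, an enzyme of serine synthesis, had 13.2, 10.5 and 22.6 RPM in KO 1 to 3 and 14.6, 29.8 and 32.8 RPM in HET 1 to 3. No target passed over all genes. Slc6a9, Eprs and Psat1, and Fbxw24 and Ddx3y further on, lie outside the rule for named genes and were chosen after their values were seen.

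A hypothesis is that ATF4 activity may be lower in KO islets. The list of 37 targets was written after Nupr1, Phgdh and Trib3 had been seen among the genes lower in KO and leaves these out, but 6 members are in lists fixed earlier whose values had been seen. The list passed camera with the preset correlation (p = 2.43e-13) but not with an estimated one (0.308, p = 0.0663), and KO 3 (0.10, centred) lay above HET 1 (-0.13). With the split as a block the camera p was 2.5e-13 preset and 0.0425 estimated, and the median -0.24. The list followed from genes seen to be low in these libraries, and each side holds a lone library of 1 genotype. The block was also chosen after seeing the data, so this result does not exclude the split as the whole cause. Of 10000 random lists matched on level, 0 had so low a median (0%). The median over all genes tested was 0.00751, so RNA relative to library totals did not fall in general. A fall of all RNA alike is removed by that scaling and cannot show here. Random lists lack the correlation between the targets, so their result does not speak for lower ATF4 activity. The hypothesis stays open.

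The split of the libraries into KO 1, KO 2 and HET 1 against KO 3, HET 2 and HET 3 may stem from a day or batch of preparation. Of biological explanations only genotype was tested, though the level of Xist, RNA of the inactive X chromosome, argues against sex as the whole cause. On the first side Xist was at 329.3 RPM in KO 1 and 0.162 RPM in HET 1. On the second it was at 295.5 RPM in HET 2 and 0.0364 RPM in KO 3. If the genotype labels are right, which Abca12 could not show, genotype as the whole cause is argued against. On the first side lay 2 KO libraries and HET 1, with a gap to the second (57.8) wider than the range within either (up to 23.3). Depth is argued against also, as 3 of the 3 totals on the first side lay within the range of the second. Acinar carry-over stays open: 3 of the 3 acinar shares on the first side (0.713%, 2.69% and 6.52%) exceeded every share on the second (0.0890% to 0.172%). From KO 1 to HET 1, though, a single pair, immediate early genes differed by a median of 0.78 and the acinar shares by 3.19 log2 units. The interval of that median, 0.60 to 1.02, is over 29 genes and not over libraries. The 3 lowest animal codes form the first side, as a shared day or batch could give, though chance gives this in 0.1 of splits and the labels state no dates. An uneven mix of the sides could account for the heat shock, antioxidant (camera block adjusted p = 0.977 each) and lactogen lists (0.889). It stays open for Schwann cell markers (0.0925), whose median went from 0.50 (0.11 to 0.96) to 0.37 (0.06 to 0.56). These ranges run from the lowest to the highest of 6 genes and are not over libraries. For beta cell identity the median hardly changed with the block, from 0.20 to 0.19. Its block adjusted p was 0.0162 by camera with the preset correlation, 0.758 with an estimated one and 0.639 by fry. The block was chosen after seeing the data and each side holds a lone library of 1 genotype. An uneven mix is therefore not excluded for that list either.

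With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split gave 0 genes and 5 lists, and the other 9 splits 0 to 4720 genes and 7 to 21 lists. Every other split thus called more lists than the real one, as could happen if the grouping were arbitrary. The 5 list calls therefore do not set genotype apart from other groupings of these libraries. The highest of the others gave 4720 genes, for the split along the first component, and 21 lists, for KO 1, KO 3 and HET 2 against the rest. The gene count of the split along the first component restates the structure of the libraries from which that split was defined.

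Fbxw15, Nnt and Wdfy1, higher in KO, could mark chromosome segments of another mouse strain that came with the floxed allele. Within 20 Mb of Abca12, 6 of 225 genes (2.67%) had an unadjusted p under 0.05, against 1.74% elsewhere (Fisher's exact test, two-sided p = 0.296), which does not decide. Over the whole genome, the 20 Mb window included, 54 pairs of such genes lay within 1 Mb of each other, against a median of 55 and a 95th percentile of 71 in 1000 random sets. The bound set in advance, at or below the median, was too weak to exclude the explanation, as 54 is well within the spread of the random sets and a few segments add few pairs. Fbxw15, Gm42755 and Fbxw24 are neighbours on chromosome 9 and differed by 1.25, 1.21 and 0.86.

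RNA from sex-linked genes differed between libraries in ways the labels do not mention. Xist, expressed from the inactive X chromosome, was at 329.3 RPM in KO 1 and 295.5 RPM in HET 2, where the Y-linked gene Ddx3y was at 0. Ddx3y was at 53.6, 102.0 and 49.7 RPM in KO 3, HET 1 and HET 3, where Xist was at most 0.162 RPM. KO 2 held both, with Xist at 459.3 RPM and Ddx3y at 49.8 RPM. Whether this library holds RNA of more than 1 animal was not tested. Without it the antioxidant, heat shock, lactogen and Schwann cell calls were lost (camera adjusted p = 0.237, 0.144, 0.215 and 0.221). Only the Schwann cell loss was particular to KO 2. The heat shock and lactogen calls were also lost without KO 1, HET 2 or HET 3, and the antioxidant call without HET 3.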
